A study of Homo sapiens with 6 samples.

How the data were processed

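RNA was sequenced from U251 glioblastoma cells transfected for 3 days with 1 ug per well of a negative control plasmid (3 libraries) or a STING overexpression plasmid (3 libraries). Per the labels' protocols, total RNA was extracted with Trizol, and libraries were made from 1 ug of it with the Illumina TruSeq RNA kit. The submitters' processing notes name Bowtie 0.12.2. The counting program, the annotation, the genome build and the strand setting are not given in the sources used here. Per the file headers, each deposited table gives, for each Ensembl gene, the authors' read counts and FPKM values with the gene's coordinates and annotation terms. The deposited counts are whole numbers that sum to between 71498790 and 76566375 per library. The deposited FPKM values were proportional to the counts, with 1 fixed length per gene, and were used only in an alternative. Of the 42307 gene identifiers 40903 were found in GENCODE v29, and 88.8% of these shared a start or end within 1 base, so coordinates are given as GRCh38. Symbols are those of the deposited tables. All rows named a gene, and every column of values belonged to a library of the series.

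Small counts were not spread evenly. Genes with a count of 4 were 1.97 to 2.29 times as frequent as the mean of those with 3 and 5, and genes with a count of 8 were 1.36 to 1.50 times as frequent as the mean of those with 7 and 9. Single counts may therefore not be independent reads, and floors of 3 counts per library are optimistic. Replicates were compared by a chi-square of their counts over 21679 genes. The chi-square per gene was 11.7 to 23.1 within groups, so no pair agreed within sampling noise and none was counted as 1 library.

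Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with the groups, TMM factors, robust quasi-likelihood fit, two-sided quasi-likelihood test with Benjamini-Hochberg adjustment, threshold 0.05). Both groups of 3 libraries entered the fit without covariates. Changes are log2 fold changes, STING plasmid over control plasmid, and CPM values use TMM-scaled library sizes. Means are given ± SD. Standard errors are the absolute log2 fold change divided by the square root of the test's F value, and so are approximate. Single values were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3 samples. The groups share replicate numbers in the labels, but no label says that a number marks a shared culture, day or batch, so the numbers were not used as a block in the main test.

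Before the data were examined, 25 gene lists with 804 members were fixed, together with the tests, the alternatives and the rule for named genes. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, at least 5 tested members), with Benjamini-Hochberg adjustment over the lists. With a correlation estimated from the libraries 0 lists passed and 1 had an unadjusted p under 0.05, and 4 passed the directional test of fry. Camera compares a list with all other genes, whereas fry tests whether the genes of a list move, on balance, in 1 direction. Members are also counted when adjusted over the list alone. The named genes were STING1; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 1 CPM, a symbol that is not clone-based, no pseudogene annotation and no overlap between the groups; the 3 tested members of each list with the smallest unadjusted p (4 for the interferon-stimulated, NF-kB and DNA sensing lists); and IFNB1, CXCL10, CCL5, CGAS, TBK1, IRF3 and IL6. This gave 99 genes. Genes named outside the rule were chosen after their values were seen. They are TAPBP, GPC1 and GYPC, models that overlap a named gene, members of enriched KEGG terms, genes of fatty acid synthesis, and TNFSF12-TNFSF13 with the genes it spans. The values of some genes that the rule named are not reported here.

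The procedure was tested on simulated data, with counts drawn from the means and library sizes of this comparison, and 20944 genes passed the filter. Genes to be changed were drawn from those with a mean of at least 1 CPM. The shares recovered below therefore do not cover lower genes, such as IFNB1 and CGAS. Of 50 genes changed by each of 4 fold sizes, 30% were recovered at 1.25-fold, 78% at 1.5-fold, 82% at 2-fold and 98% at 3-fold, and 4.64% of the calls were false. With no gene changed 0 were called. A simulated GC trend in 1 group gave 961 false calls, and 1 after the correction used here. The correction removes trends in GC content, so this test could hardly have given another result. In the real data the trend with GC content was positive in STING library 1 and negative in STING libraries 2 and 3. A trend that differs within a group was not simulated. The shares recovered and false hold for simulated counts and may be optimistic for the real libraries.

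The alternatives were RLE, upper-quartile and total-count scaling, no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a log2 fold change of at least 1, an adjusted p under 0.01, and for lists an estimated correlation, fry, and the removal of genes in more than 1 list. Alternatives added after seeing the data were a correction for GC content and length within each library (natural splines with 5 degrees of freedom, with and without mean abundance), counts divided by 4, and limma-trend on log2(FPKM + 0.1). GC content came from GENCODE v29 transcripts and was known for 97.9% of tested genes. List medians were also set against 10000 random lists matched on GC content, length and expression, and the real list was counted in each share. Members were drawn independently, so the random medians do not carry the correlation between genes of a list. KEGG terms of the deposited annotation were tested with Fisher's exact test in scipy 1.17.1 against the 5890 tested genes that carry a term, an analysis chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.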

Results

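RNA sequencing measured gene expression in U251, an established human glioblastoma cell line. Cells had been transfected for 3 days with 1 ug per well of a negative control plasmid or of a plasmid for overexpression of STING, the adaptor protein of the pathway that senses cytosolic DNA. There were 3 libraries per group. The deposited tables listed 42307 genes. Their counts summed to 74638335, 71498790 and 76158548 in control libraries 1, 2 and 3 and to 76566375, 75660766 and 75605739 in STING libraries 1, 2 and 3. Levels are given in CPM, counts scaled to the library size, and at these depths 3 counts corresponded to 0.0392 to 0.042 CPM, a floor that covers counting error only. The labels do not say that the replicates were separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical. Camera p-values also rest on the spread among genes, which the preset correlation of 0.01 takes as nearly independent. The correlation estimated from the libraries was 0.303 for the cholesterol biosynthesis list and 0.654 for the interferon-stimulated list.

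The comparison asked how the STING plasmid changed the transcriptome of these cells, and STING1, the gene on the plasmid, was examined first. STING1 (ENSG00000184584) lies on the minus strand of chromosome 5 between 139475533 and 139482935, in coordinates that match GRCh38. It was counted 2660, 2628 and 2360 times in the control libraries and 4327, 4226 and 3596 times in the STING libraries. Its level rose 1.51-fold, from 34.8 ± 3.15 to 52.8 ± 4.79 CPM (SD, n = 3 per group). The log2 fold change was 0.60 with a standard error of 0.078, and the adjusted p was 0.00221 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The lowest STING library lay 1.28 times above the highest control library. A two-sided exact permutation test of the CPM values gave p = 0.1, the smallest that 3 against 3 samples allow. The counts do not separate transcripts of the plasmid from those of the chromosomal gene.

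With the STING plasmid 131 genes rose and 193 fell among 21679 tested genes, and most of these changes were small. The median absolute log2 fold change of the 324 changed genes was 0.29. CCL5, a chemokine that attracts T cells (ENSG00000271503, chromosome 17, 35871491 to 35880793), rose 2.05-fold, from 3.01 ± 0.134 to 6.19 ± 0.369 CPM (SD, n = 3), with an edgeR adjusted p of 0.00248. DHRS2, a short-chain dehydrogenase (ENSG00000100867, chromosome 14, 23630115 to 23645639), rose 1.74-fold, from 47.0 ± 1.99 to 81.9 ± 4.12 CPM, with an edgeR adjusted p of 2.82e-06. COL18A1, which encodes a basement membrane collagen (ENSG00000182871, chromosome 21, 45405165 to 45513720), fell from 27.6 ± 1.07 to 16.6 ± 0.722 CPM, with an edgeR adjusted p of 0.000118. GFAP, the intermediate filament of astrocytes (ENSG00000131095, chromosome 17, 44903159 to 44916937), fell from 39.1 ± 3.98 to 21.5 ± 3.88 CPM, with an edgeR adjusted p of 0.033.

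The genes listed next have a mean of at least 1 CPM and a symbol that is not clone-based. Some genes outside this rule changed more. Other large rises were those of ACTN2, a muscle-type actinin (2.10-fold), the chemokine CXCL11 (1.79-fold) and the noncoding RNAs LINC00520 (1.76-fold) and LINC02154 (1.65-fold). The protease ADAMTS6 (1.64-fold), PSG9 (1.63-fold) and the zinc finger gene ZNF114 (1.57-fold) rose too. Other large falls were those of the fatty acid desaturase FADS2 (to 0.576 of the control level), the retinol transporter STRA6 (to 0.565), LSP1 (to 0.391), ADAMTS10 (to 0.555), DHRS3 (to 0.627) and A4GALT (to 0.63). PSG9 belongs to a family of near-identical genes, and FADS2 overlaps FADS1 on the opposite strand, so their values are uncertain. The sum of FADS2 and FADS1 also fell, from 401 ± 24.3 to 287 ± 22.75 CPM (SD, n = 3). The groups did not overlap, which argues against reads moving between these models as the whole cause. Of the 20 genes with the largest changes 9 overlap another tested model. Among them CCL5, COL18A1, GFAP and LSP1 still separated the groups when summed with such models. HSH2D (1.69-fold higher) overlaps the far more abundant RAB8A, at 133 CPM in the controls, and PRC1-AS1 (0.442 of the control level) is antisense to PRC1, at 193 CPM. The fall of SEPTIN5 to 0.347 of the control level is uncertain too. The overlapping model AC000093, named like FADS1, RAB8A and PRC1 after the values were seen, rose from 1.14 ± 0.307 to 2.68 ± 0.147 CPM, and the sum of both was 3.69 ± 0.549 in the controls and 3.56 ± 0.164 with the STING plasmid (SD, n = 3).

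The split between higher and lower genes depended on the scaling, since scaling to total counts alone gave 246 higher and 138 lower genes. The number of changed genes was 324 with all libraries and changed when 1 was left out. A smaller group also lowers the power of the test, so a lower number does not by itself mark a deviating library. The number was 60, 60 and 104 without control library 1, 2 or 3, and 741, 95 and 163 without STING library 1, 2 or 3. It rose only without STING library 1. Of the 57 named genes that changed, 14 also passed the threshold without each of the 6 libraries in turn, and each of the others lost it without at least 1. Among these 14 were STING1, CCL5, DHRS2, LINC02154, LINC00520, ZNF114, ADAMTS6, COL18A1, COL6A2, HMGCS1, DHCR7, H2AC6 and MT-ND6. The number that passed was 18, 21 and 26 without control library 1, 2 or 3 and 46, 27 and 29 without STING library 1, 2 or 3.

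**Figure D1:**
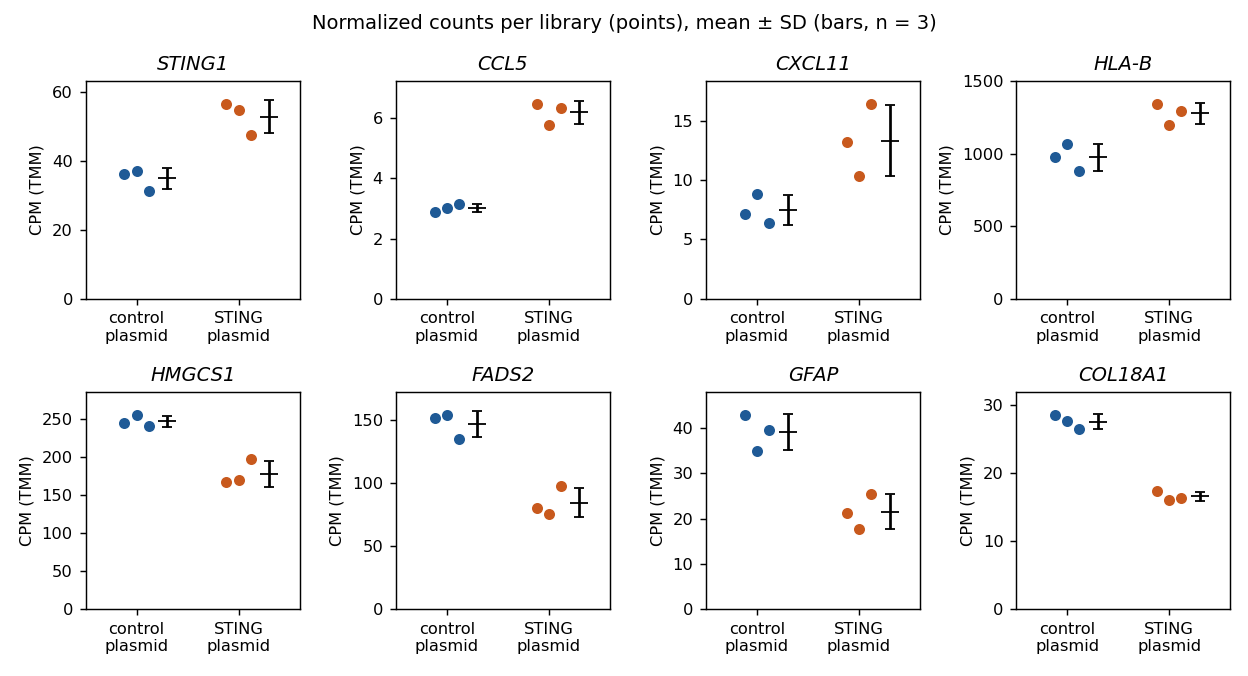
Levels of 8 named genes in CPM after TMM scaling (y axes, from 0), with 1 point per library for the control plasmid (blue) and the STING plasmid (orange). Black bars give the mean ± SD (n = 3). In each panel the points of the groups do not overlap, as for CCL5 at 3.01 against 6.19 CPM. That holds for all 324 changed genes, so it adds no support. It holds for 19.9% of the tested genes, against 10% expected by chance.

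Interferon-stimulated genes lay slightly higher with the STING plasmid, although few changed one by one. Of 48 tested members 2 rose, 0 fell and 46 did not pass the test, and 6 rose when adjusted over the list alone. An unadjusted edgeR p under 0.05 was reached by 18 members, DESeq2 called 11 higher and 1 lower, and limma-voom called 0. The risen members were CXCL11, a chemokine induced by interferon gamma (7.46 ± 1.28 to 13.3 ± 3.01 CPM, edgeR adjusted p = 0.0436), and USP18, a protease that removes ISG15 from proteins (85.9 ± 6.18 to 106 ± 9.16 CPM, edgeR adjusted p = 0.044). The RNA sensor IFIH1 had a log2 fold change of 0.22 (SE 0.056, edgeR adjusted p = 0.0645) and SP110 one of 0.22 (SE 0.061, edgeR adjusted p = 0.0906). The estimate was positive for 41 of the 48 members, and the list median was 0.13 on the log2 scale. The list passed camera (adjusted p = 7.02e-06) but not with an estimated correlation (adjusted p = 0.652 with an estimated correlation) and not fry (adjusted p = 0.377). Without STING library 3 the median was 0.065.

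The interferon gene IFNB1 was low in both groups, at 0.740 ± 0.299 CPM with the control plasmid and 0.709 ± 0.167 CPM with the STING plasmid (SD, n = 3, edgeR adjusted p = 0.973). Of the 9 testable interferon genes and receptors 0 changed, 0 had an unadjusted edgeR p under 0.05, and 0 passed in DESeq2 or limma-voom. Their median log2 fold change was −0.07 (camera adjusted p = 0.155, and 0.0366 and 0.0262 after correction for GC content and length without and with abundance), and adjusted over the list alone 0 changed. The median was −0.0294 without control library 3, −0.0343 without a filter on low counts, −0.0427 with scaling to total counts, and −0.115 and −0.121 with the corrections. IFNAR1, IFNGR2 and IL10RB, which encode receptor chains, had log2 fold changes of −0.07, −0.12 and −0.08. With 1 library left out they ranged from −0.0948 to −0.0402, −0.194 to −0.0387 and −0.130 to −0.0512. The chemokine CXCL10 was at 19.3 ± 4.71 and 27.4 ± 7.78 CPM (edgeR adjusted p = 0.578), and the cytokine IL6 at 13.0 ± 1.43 and 15.4 ± 1.55 CPM (edgeR adjusted p = 0.308).

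Among 38 DNA sensing and STING pathway components 1 rose (USP18), 0 fell and 37 did not pass the test. Adjusted over the list alone 1 rose and 1 fell. The list median was −0.05 (camera adjusted p = 0.165). The kinase TBK1 had a log2 fold change of 0.05 (SE 0.051), the transcription factor IRF3 one of −0.06 (SE 0.047) and the kinase IKBKE one of −0.32 (SE 0.082, edgeR adjusted p = 0.0679). SAR1A had a log2 fold change of 0.13. CGAS was low in both groups, at 0.360 ± 0.0706 and 0.494 ± 0.222 CPM. Of 39 NF-kB target genes 1 rose (CCL5), 1 fell (IL32, from 28.4 ± 3.35 to 21.6 ± 1.22 CPM) and 37 did not pass, with 1 higher and 3 lower when adjusted over the list alone. ICAM1 and LIF had log2 fold changes of −0.37 and −0.20. The NF-kB list median was −0.02 (camera adjusted p = 0.431) and changed sign under scaling to total counts. Without control library 3 that list passed camera, with a median of −0.0686 (adjusted p = 0.0407).

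Of 20 tested genes of MHC class I antigen presentation 4 rose, 1 fell and 15 did not pass the test, and 8 rose and 1 fell when adjusted over the list alone. With the correction for GC content and length, chosen after the data were seen, 7 were called higher and 0 lower. HLA-B rose 1.31-fold, HLA-C 1.20-fold and HLA-F 1.24-fold, with edgeR adjusted p of 0.0214, 0.0213 and 0.029. TAPBP, which helps load peptides onto class I molecules, fell to 0.819 of the control level, lost its call with that correction and was chosen after its value was seen. The HLA genes are highly similar and vary between cell lines, so reads can be split between them and their values are uncertain. The list median was 0.11 (camera adjusted p = 0.0422, adjusted p = 0.689 with an estimated correlation, and fry adjusted p = 0.428). With the correction for GC content and length it was 0.0952 (camera adjusted p = 0.00159), and with abundance included 0.172 (2.18e-07). The list did not pass camera without control library 3 (median 0.0562, adjusted p = 0.179), STING library 1 (0.109, adjusted p = 0.23) or STING library 3 (0.0703, adjusted p = 0.35). Nor did it pass without a filter on low counts, with the stricter filter or with the replicate number as a block (adjusted p of 0.0613, 0.0538 and 0.0907).

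Genes of cholesterol biosynthesis were lower together with the STING plasmid. Of 24 tested members 0 rose, 11 fell and 13 did not pass the test, and 20 fell when adjusted over the list alone. HMGCS1, which makes HMG-CoA for the mevalonate pathway (ENSG00000112972, chromosome 5, 43287470 to 43313512), fell from 247 ± 7.52 to 178 ± 17.1 CPM (SD, n = 3, edgeR adjusted p = 0.00174). DHCR7, the enzyme of the last step to cholesterol in one branch, fell from 130 ± 7.07 to 97.0 ± 7.07 CPM (edgeR adjusted p = 0.00249). All 24 estimates were negative, with a median log2 fold change of −0.26. The list passed camera (adjusted p = 4.03e-14, and adjusted p = 0.397 with an estimated correlation) and the directional test of fry (adjusted p = 0.0376). Without each library in turn its median lay between −0.30 and −0.23. The 10 most abundant genes took 5.45 ± 0.0601% of all counts in the controls and 4.94 ± 0.168% with the STING plasmid, and the TMM factors were 0.990 ± 0.00379 and 1.011 ± 0.0104 (SD, n = 3 per group, two-sided exact permutation p = 0.1 for each). Both measures separated the groups without overlap, as did the shares of mitochondrial and histone counts.

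Several groups tied to the extracellular matrix, glial identity and glucose metabolism were lower. Of 50 extracellular matrix and mesenchymal genes 0 rose, 6 fell and 44 did not pass, with 4 higher and 18 lower when adjusted over the list alone. COL6A2 fell from 93.7 ± 2.76 to 73.3 ± 4.51 CPM, COL6A1 from 108 ± 4.49 to 89.3 ± 2.95 CPM, and the membrane-bound metalloprotease MMP14 from 173 ± 9.09 to 138 ± 5.28 CPM. The list median was −0.12 (camera adjusted p = 0.000121, and adjusted p = 0.397 with an estimated correlation), and fry gave an adjusted p of 0.0376. Of 23 astrocyte and glioma markers 3 fell (GFAP, ID1 and ID3), 0 rose and 20 did not pass, with 5 lower when adjusted over the list alone. ID1 and ID3, inhibitors of helix-loop-helix transcription factors, fell to 0.834 and 0.831 of the control level. That list's median was −0.10 (camera adjusted p = 0.00188, adjusted p = 0.397 with an estimated correlation, and fry adjusted p = 0.0556).

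Of 32 hypoxia and glycolysis genes 3 fell, 0 rose and 29 did not pass, with 11 lower when adjusted over the list alone. The glycolytic genes PKM, HK1 and ENO1 fell to 0.849, 0.865 and 0.866 of the control level. The list median was −0.11 (camera adjusted p = 0.00127, adjusted p = 0.652 with an estimated correlation, and fry adjusted p = 0.347). Without STING library 2 the median was −0.0578 (adjusted p = 0.0387), and after correction for GC content and length it was −0.0805 and the list did not pass (adjusted p = 0.121). Of 21 metallothionein and NRF2 target genes 3 fell, 0 rose and 18 did not pass, with 7 lower when adjusted over the list alone. Among the fallen members were the ferritin heavy chain FTH1 and the pentose phosphate enzyme TKT, to 0.844 and 0.808 of the control level, and none was a metallothionein. That list's median was −0.04 (camera adjusted p = 0.00918, adjusted p = 0.397 with an estimated correlation, and fry adjusted p = 0.0762), and −0.0714 and −0.0804 without STING library 1 or 3. It was −0.0052 with scaling to total counts and −0.0895 with the stricter filter. Of 10000 random lists matched on GC content, length and expression, 44.8% had a median as low as that of the metallothionein and NRF2 list, against 0.75% for the hypoxia and glycolysis list and 2.72% for the astrocyte list. When GC content, length and mean abundance were all corrected, the extracellular matrix, astrocyte and metallothionein and NRF2 lists did not pass camera (adjusted p of 0.194, 0.152 and 0.579), with medians of −0.0797, −0.0582 and −0.0482. The median of the hypoxia and glycolysis list was then −0.0315 (adjusted p = 0.364). The changed genes differed in base composition: median GC content was 48.6% over all genes, 45.2% in the risen and 56.8% in the fallen genes. The change per 10% of GC content was 0.0149, 0.0469 and 0.0197 on the log2 scale in the control libraries and 0.0338, −0.0728 and −0.0425 in STING libraries 1, 2 and 3.

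Mitosis genes lay lower with the STING plasmid, although few changed one by one in the main test. Of 38 G2/M and mitosis genes 0 rose, 3 fell and 35 did not pass, with 12 lower when adjusted over the list alone. With the correction for GC content and length, chosen after the data were seen, 12 were called lower and 0 higher over all genes. The mitotic kinase PLK1 fell from 117 ± 2.75 to 97.4 ± 3.24 CPM, the APC/C activator CDC20 from 183 ± 7.72 to 152 ± 10.2 CPM, and the kinesin KIF20A from 140 ± 5.27 to 121 ± 5.50 CPM. Of the 38 estimates 36 were negative, with a median of −0.12 (camera adjusted p = 1.3e-08, adjusted p = 0.397 with an estimated correlation, and fry adjusted p = 0.0762). Of 40 DNA replication genes 1 rose (SLBP, which binds the stem-loop of histone transcripts, 1.14-fold), 0 fell and 39 did not pass, with 5 higher when adjusted over the list alone. ORC6 and CDC6 had log2 fold changes of 0.20 and 0.16 (edgeR adjusted p of 0.0556 and 0.0996). That list's median was 0.04 (camera adjusted p = 0.0434, adjusted p = 0.64 with an estimated correlation, and fry adjusted p = 0.197), 0.0661 with scaling to total counts and 0.0567 on the authors' FPKM. It did not pass without control library 1, control library 2 or STING library 1 (medians of 0.0373, 0.0277 and 0.0314, adjusted p of 0.0687, 0.196 and 0.31), nor with upper-quartile scaling, with either other filter, with the replicate number as a block or with counts divided by 4.

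Replication-dependent histone genes, whose reads are easily shared between copies, are uncertain. Of 15 tested members 1 rose (H2AC6, from 30.8 ± 1.18 to 41.2 ± 3.15 CPM), 0 fell and 14 did not pass, with 3 higher when adjusted over the list alone. H4C8 and H2BC5 had log2 fold changes of 0.62 and 0.44 (edgeR adjusted p of 0.0697 and 0.104). The histone list median was 0.22 (camera adjusted p = 0.0298, adjusted p = 0.397 with an estimated correlation, and fry adjusted p = 0.0376), and the list did not pass without control library 2 or STING library 1 (adjusted p of 0.0529 and 0.0818), with medians of 0.231 and 0.303. Histone genes took 0.00811, 0.00851 and 0.00802% of all counts in the control libraries and 0.0106, 0.00946 and 0.0101% in the STING libraries (two-sided exact permutation p = 0.1).

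Of 26 p53 target genes 2 rose, 0 fell and 24 did not pass, with 2 higher and 1 lower when adjusted over the list alone. GADD45A, induced by DNA damage and stress, rose 1.24-fold and the BH3-only gene PMAIP1 rose 1.23-fold, while CCNG1 had a log2 fold change of −0.21 (edgeR adjusted p = 0.0597). The p53 list median was −0.02, its mean was 0.000656 and camera gave the upward direction (adjusted p = 0.962); the median changed sign under scaling to total counts. PMAIP1 was also the 1 riser of 34 apoptosis and cell death genes, of which 0 fell and 33 did not pass, with 1 higher when adjusted over the list alone. MLKL and CYCS had log2 fold changes of 0.25 and 0.15, and the list median was 0.04 (camera adjusted p = 0.414).

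Of 40 autophagy and lysosome genes 1 rose (RRAGD, 1.15-fold), 1 fell and 38 did not pass, with 3 higher and 3 lower when adjusted over the list alone. The lysosomal protease CTSD fell from 688 ± 32.9 to 538 ± 40.7 CPM (edgeR adjusted p = 0.00538), and CTSB had a log2 fold change of −0.19 (edgeR adjusted p = 0.0508). Over the whole list the median was −0.04 (camera adjusted p = 0.546). It was −0.0192 and −0.0134 without control library 1 or 2 and −0.0669 and −0.0158 without STING library 1 or 2. Of 33 genes of the unfolded protein response 0 passed in edgeR and 12 had an unadjusted p under 0.05, while DESeq2 called 4 higher and 1 lower and limma-voom 0. Adjusted over the list alone 3 were higher, and the median was 0.03 (camera adjusted p = 0.233, and 0.0685 with adjusted p = 0.0262 after correction for GC content, length and abundance). ATF3, DDIT3 and PPP1R15A, transcripts of the integrated stress response, had log2 fold changes of 0.23, 0.18 and 0.21 (edgeR adjusted p of 0.0762, 0.0846 and 0.107). Of 30 immediate early genes 0 passed in edgeR, 4 had an unadjusted p under 0.05, DESeq2 called 1 higher and limma-voom 0, and 0 changed when adjusted over the list alone. FOSB and KLF4 had log2 fold changes of 0.57 and 0.35, which ranged from 0.333 to 0.680 and from 0.267 to 0.478 with 1 library left out. FOSB was at 7.02, 4.58 and 4.53 CPM in STING libraries 1, 2 and 3. The list median was 0.01 (camera adjusted p = 0.155). The immediate early list passed camera without STING library 3 (median 0.0365, adjusted p = 0.0348) and with the correction for GC content and length, without abundance (median 0.0626, adjusted p = 0.001) and with it (median 0.0568, adjusted p = 0.00143), both chosen after the data were seen.

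Of 18 heat shock genes 2 fell, 0 rose and 16 did not pass, with 3 lower when adjusted over the list alone. The small heat shock gene CRYAB fell to 0.687 and the co-chaperone DNAJB1 to 0.88 of the control level, while HSPB1 had a log2 fold change of −0.19 (edgeR adjusted p = 0.0871). The heat shock median was −0.02 (camera adjusted p = 0.233) and changed sign under scaling to total counts. Of 44 oxidative phosphorylation genes 0 passed in edgeR, 7 had an unadjusted p under 0.05, DESeq2 called 1 higher and 1 lower and limma-voom 0, and 0 changed when adjusted over the list alone. SDHC, COX7B and COX6B1 had log2 fold changes of −0.19, 0.15 and −0.14, and COX6B1 ranged from −0.208 to −0.0738 with 1 library left out. The oxidative phosphorylation median was −0.03 (camera adjusted p = 0.371) and also changed sign under scaling to total counts.

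Transcripts of the mitochondrial genome were lower with the STING plasmid. Of 13 protein-coding genes 6 fell, 0 rose and 7 did not pass, and 12 fell when adjusted over the list alone. MT-ATP6 fell from 3301 ± 54.6 to 2724 ± 149 CPM and MT-CO3 from 3087 ± 48.6 to 2597 ± 90.6 CPM. MT-ND6 fell to 0.817 of the control level, but it is the 1 gene of the opposite strand and is uncertain because the strand setting of the counts is not given in the sources used here. Over the 13 genes the median was −0.155 (camera adjusted p = 2.81e-08, adjusted p = 0.397 with an estimated correlation, and fry adjusted p = 0.0419), and the list did not pass camera when GC content, length and abundance were corrected (median −0.104, adjusted p = 0.194). The mitochondrial genome took 4.40 ± 0.072% of all counts in the controls and 3.91 ± 0.159% with the STING plasmid (SD, n = 3, two-sided exact permutation p = 0.1). Of 78 cytoplasmic ribosomal protein genes 2 fell (RPSA and RPS2, to 0.862 and 0.864 of the control level), 0 rose and 76 did not pass, with 3 lower when adjusted over the list alone. RPLP0 had a log2 fold change of −0.18 (edgeR adjusted p = 0.0771). The ribosomal list median was −0.02 (camera adjusted p = 0.0606), and it changed sign under scaling to total counts. These genes have many pseudogenes and are uncertain. That list passed camera without control library 1 or STING library 1 (medians of −0.0625 and −0.0715, adjusted p of 0.000556 and 0.000199), and with RLE or upper-quartile scaling and limma-voom.

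Markers of other cell types showed few changes. Of 14 neuronal markers 0 passed in edgeR, 2 had an unadjusted p under 0.05, and 0 passed in DESeq2, in limma-voom or when adjusted over the list alone. MAP2 and GAD1 had log2 fold changes of 0.18 and 0.16, which ranged from 0.0916 to 0.241 and from 0.0955 to 0.214 with 1 library left out. DCX was at 0.0272 ± 0.0471 and 0.170 ± 0.0136 CPM (edgeR adjusted p = 0.303), and the list median was 0.10 (camera adjusted p = 0.371). Of 18 epithelial markers 1 fell (KRT15, to 0.726 of the control level), 0 rose and 17 did not pass, with 1 lower when adjusted over the list alone. ELF3 had a log2 fold change of −0.34, and the median was −0.05 (camera adjusted p = 0.425). Of 18 hematopoietic markers 0 passed in edgeR, 0 had an unadjusted p under 0.05, and 0 passed in DESeq2, in limma-voom or when adjusted over the list alone. LCP1, CORO1A and CD4 had log2 fold changes of −0.30, −0.53 and −0.75. With 1 library left out they ranged from −0.427 to −0.166, −0.852 to −0.318 and −1.006 to −0.637. The list median was −0.38 (camera adjusted p = 0.114). That list passed camera without control library 1 (median −0.67, adjusted p = 0.000556) or STING library 3 (−0.655, adjusted p = 0.0106), but its median was −0.067 without control library 2 (adjusted p = 0.583) and −0.226 without STING library 1 (adjusted p = 0.408). It also passed with scaling to total counts, with limma-trend on the authors' FPKM and with the replicate number as a block (adjusted p of 0.0432, 0.0326 and 0.0208).

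In most lists DESeq2 called more members than edgeR and limma-voom fewer. DESeq2 called 18 cholesterol biosynthesis, 11 mitosis, 9 hypoxia and glycolysis, 7 metallothionein and NRF2, 5 astrocyte and 11 mitochondrially encoded genes lower and 0 higher, and limma-voom called 7, 1, 1, 2, 1 and 6 of them lower. Of the extracellular matrix genes DESeq2 called 2 higher and 14 lower and limma-voom 5 lower, and of the MHC class I genes DESeq2 called 9 higher and 1 lower and limma-voom 1 higher. DESeq2 called 6 DNA replication and 3 histone genes higher, and limma-voom 0 and 1. DESeq2 called 1 NF-kB target higher and 4 lower, 2 DNA sensing components higher and 3 lower, 2 autophagy and lysosome genes higher and 3 lower, and 8 cytoplasmic ribosomal genes lower.

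**Figure D2:**
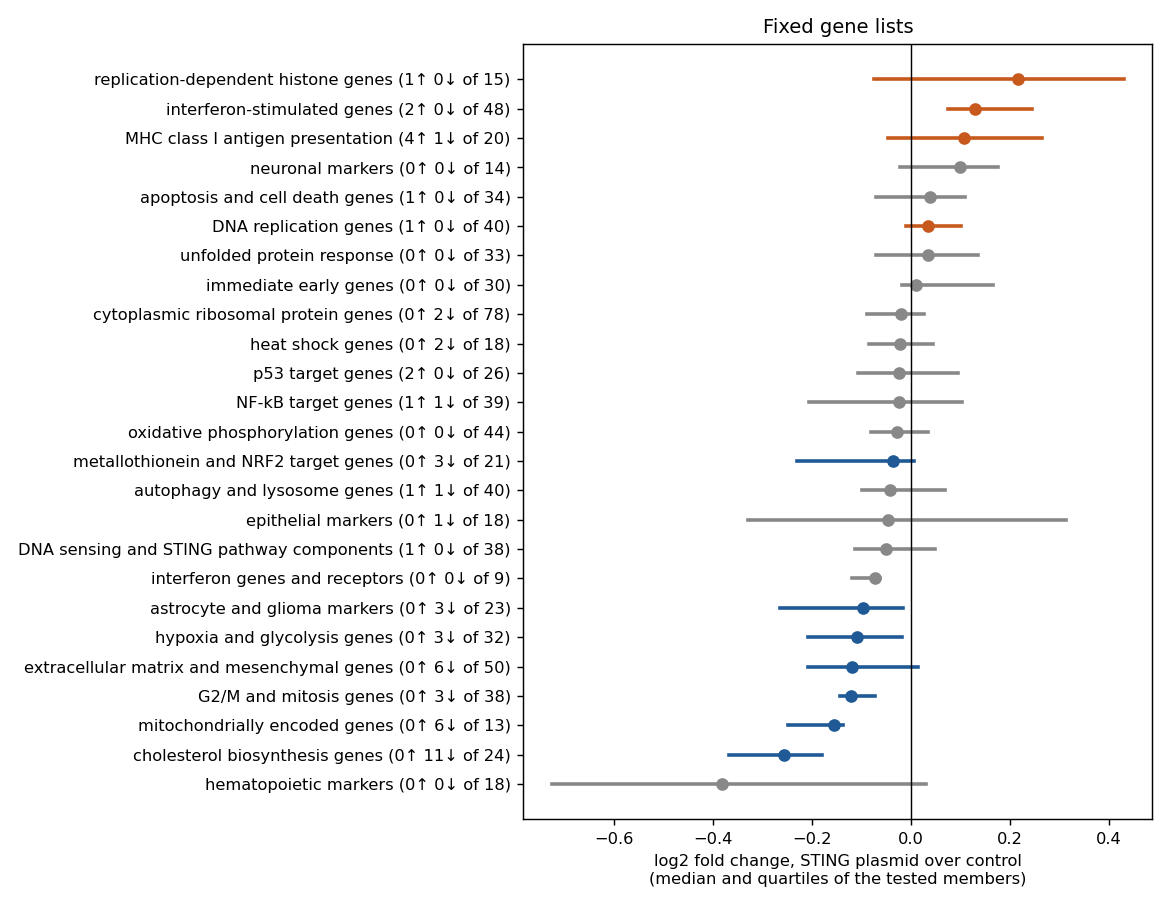
Median (point) and quartiles (line) of the log2 fold change, STING plasmid over control plasmid (x axis), for the tested members of 25 gene lists (y axis), with the numbers of members that rose and fell. Colours mark the 11 lists that passed camera (orange higher, blue lower), and the cholesterol biosynthesis list has the lowest median among these, at −0.26.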

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

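The tests with corrections for GC content, with counts divided by 4 and with the authors' FPKM were chosen only after the result was seen. STING1 was higher in all 18 refits and other gene tests and past the threshold in each except limma-trend on the authors' FPKM, with a log2 fold change of 0.61 there (adjusted p = 0.101). Its log2 fold change of 0.60 lies under the stricter threshold of 1, and its adjusted p of 0.00221 under that of 0.01. Of the 57 named genes past the threshold 0 changed direction in these 18, and 4 (CCL5, DHRS2, LINC02154 and ZNF114) stayed past it in all 18, which leave out the stricter thresholds. The 131 higher and 193 lower genes moved by less than 1.5 times with RLE or upper-quartile scaling, without a filter and with either GC correction; 263 of the 324 genes were also called with the correction for GC content and length. Scaling to total counts gave 246 higher genes. A filter of at least 1 CPM in 3 libraries gave 274 higher and 412 lower genes, DESeq2 398 and 524, limma-voom 58 and 79, and counts divided by 4 263 and 381. Limma-trend on FPKM gave 8 and 1, the latter being GPC1, named after its value was seen. The stricter thresholds give fewer by construction: 13 and 4 at an absolute log2 fold change of at least 1, the latter being SEPTIN5, LSP1, PRC1-AS1 and GYPC (named after its value was seen), and 30 and 38 at an adjusted p under 0.01. With 1 library left out there were 34 to 260 higher and 26 to 481 lower genes, most without STING library 1 and fewest without control library 1 or 2. For these other changes of count the cause was not tested.

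With the replicate number as a block there were 55 higher and 65 lower genes, and of the 57 named genes past the threshold 28 also passed and 29 did not. The deviations of samples with the same number correlated at 0.0551, 0.0231 and 0.0172, so the numbers do not pair the samples by the limit of 0.1. Of the 6 samples 5 correlated best with their own number, the exception being STING library 3 (0.0192 with control library 2), a hint from the data and not from the design. Of the 11 lists past camera 0 also passed with an estimated correlation, 4 with fry, 6 with the correction for GC content, length and abundance, 8 without STING library 1, and 9 to 11 under each of the other alternatives. Lists not past camera in the full comparison passed as well under some of these, at most 4 of them, with the correction that includes abundance. The MHC class I and DNA replication lists also lost their call without a filter, with the stricter filter and with the block, and with either GC correction the hypoxia and glycolysis list did. With abundance included, the extracellular matrix, metallothionein and NRF2, astrocyte and mitochondrial lists did too.

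Estimates that changed sign were all of genes or lists not past the threshold, and the cause was not tested. IRF3 was at 0.0253 and 0.0231 with the GC and length correction without and with abundance. IFNB1 lay between −0.306 and 0.288 with 1 library left out, and at 0.0167 on FPKM. With scaling to total counts the medians of the NF-kB, p53, oxidative phosphorylation, heat shock and cytoplasmic ribosomal lists were 0.00494, 0.00763, 0.00157, 0.00836 and 0.0102. With the correction that includes abundance the DNA sensing, autophagy, heat shock, epithelial and ribosomal lists were at 0.00144, 0.00788, 0.00854, 0.0369 and 0.0229, and the ribosomal list then passed camera (adjusted p = 0.00015, against 0.000199 to 0.622 with 1 library left out). The epithelial list was at 0.021 with the GC and length correction and 0.116 without a filter, and on FPKM the NF-kB and ribosomal lists were at 0.00427 and 0.00155. With 1 library left out the list medians ranged from −0.0826 to 0.0157 (NF-kB), −0.0395 to 0.00219 (p53), −0.0135 to 0.0516 (apoptosis), −0.00898 to 0.178 (neuronal), −0.232 to 0.168 (epithelial) and −0.0715 to 0.00811 (ribosomal). Without a change of sign they ranged from −0.0895 to −0.0294 (interferon genes and receptors), −0.0489 to −0.0262 (DNA sensing), 0.0128 to 0.076 (unfolded protein response), −0.0669 to −0.0134 (autophagy and lysosome), −0.0516 to −0.0111 (oxidative phosphorylation), 0.0127 to 0.0395 (immediate early) and −0.0446 to −0.00563 (heat shock). At these depths levels under 0.0392 to 0.042 CPM (3 counts) were not detectable. Of the 27 listed interferon genes and receptors 9 were testable.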

Other observations

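The tests of KEGG terms, of overlapping gene models and of the scaling of the cholesterol list, the corrections for GC content and length, and the tests of the fatty acid list other than matched random lists, were chosen only after the result was seen.

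Terms for the attachment of cells to the matrix were enriched among the fallen genes. Of 309 KEGG terms tested in each direction, 11 were enriched among the changed genes, and 28 after the correction for GC content and length. All p-values here are from Fisher's exact test with Benjamini-Hochberg adjustment, which treats genes as independent. The smallest was that of steroid biosynthesis, with 6 fallen genes, DHCR7 among them, against 0.35 expected (adjusted p = 0.000415). Several of the 11 terms, such as antigen processing and presentation, held the same 4 risen HLA genes. The focal adhesion term held 13 of the 113 fallen genes with a term against 3.38 expected (adjusted p = 0.00283), among them the actins ACTB and ACTG1, the actinins ACTN1 and ACTN4, the actin crosslinker FLNA and the integrins ITGAV, ITGB4 and ITGB5. After the correction for GC content and length it held 15 (adjusted p = 0.00298), without ACTN1 and FLNA. The ECM-receptor term held 7 fallen genes against 1.27 expected (adjusted p = 0.0167), and 10 after the correction. COL6A1, COL6A2 and TNC, counted in both terms before the correction, also belong to the extracellular matrix list. Of the 46 risen genes with a term 13 belonged to the herpes simplex virus 1 term against 3.46 expected (adjusted p = 0.00283), among them STING1, CCL5, SRSF7, HLA-B, HLA-C and HLA-F and the zinc finger genes ZNF114, ZNF419, ZNF473, ZNF550, ZNF616 and ZNF675. STING1 is the gene on the plasmid, so its rise lends this term no weight, and the values of the HLA genes are uncertain.

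The fall of the cholesterol biosynthesis list was weighed against technical explanations. The list median of −0.257 moved to −0.252 after correction for GC content and length. With the real list counted in, 0.01% of 10000 matched random lists had a median as low (1e-04, the smallest share the draws can give). The list median was −0.227 or lower under 3 other scalings, and no single library left out brought it closer to 0 than −0.228 (without STING library 2). The values other than those of the scalings argue against base composition and 1 deviating library as the whole cause. The scalings moved the median log2 fold change of all tested genes only from 0.00103 to −0.00175, −0.00875 and 0.0313. Their test could therefore hardly have given another result and does not decide on scaling. A hypothesis formed after FASN and FADS2 were seen among the fallen genes was that the lower expression extends to fatty acid synthesis. In a list of 22 genes of fatty acid and glycerolipid synthesis without these 2, 19 estimates were negative. Of the 22 genes 2 fell (ACACA and FADS1), and 7 fell when adjusted over the list alone. The median was −0.122. With the real list counted in, 0.01% of matched random lists lay as low (the smallest share the draws can give). FADS1 overlaps FADS2, and without it 21 genes had a median of −0.121, 1 fell, and 6 fell when adjusted over the list alone. The share of matched random lists as low, the real list counted in, was again 0.01%. For the 22 genes the unadjusted p was 1.71e-06 in camera, 0.0892 with an estimated correlation and 0.0136 in fry, so the hypothesis of a shared decrease stays open. The groups also differed in the share of the 10 most abundant genes (5.45 against 4.94% of counts) and of the mitochondrial genome (4.40 against 3.91%). What these or other differences between the samples contribute stays open.

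The higher interferon-stimulated genes were weighed against base composition and single libraries. After correction for GC content and length the list median was 0.132, against 0.129 before. With the real list counted in, 0.01% of matched random lists lay as high (the smallest share the draws can give). Both values argue against base composition as the cause. Without STING library 3 the median was 0.065 and without control library 3 it was 0.0941. The bound set in advance was 0.5 times the full median, or 0.0645. The value without STING library 3 lies within its bootstrap standard error of 0.0171 of that bound, a condition added after the value was seen, so a single deviating library cannot be told apart from an effect of the plasmid.

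The read-through gene TNFSF12-TNFSF13 (chromosome 17, 7549099 to 7561601, plus strand) was counted 0 times in each control library and 141, 141 and 93 times in the STING libraries. It spans TNFSF12 and TNFSF13. The summed CPM of the 3 models was 29.09, 27.88 and 27.79 in control libraries 1, 2 and 3. In STING libraries 1, 2 and 3 it was 28.52, 22.94 and 24.65, the highest being 0.98 times the highest of the controls. The read-through gene itself was at 1.84, 1.82 and 1.22 CPM there, less than the spread of these sums. Reads may have been assigned differently between overlapping models, but the sums cannot decide it. For SEPTIN5 and the overlapping AC000093 means were compared instead. Their mean summed CPM with the STING plasmid was 0.966 times that of the controls, as reads moving between models would give. At a minimum of 20 counts in each library of 1 group and 0 in the other, 1 gene separated the real groups, and each of the 9 other splits had at least 1 such gene. No biological explanation was tested.

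Only 10 splits of the 6 libraries into 3 and 3 exist, so no share under 0.05 can be reached. The real split gave 324 changed genes and the highest other split 2, so 1 of the 10 splits gave as many. For lists past camera the real split gave 11 and the other splits 4, 3, 11, 8, 5, 6, 2, 5 and 4, so 2 of the 10 gave as many. Lists thus passed camera under every arbitrary split too. The other split with 11 set control libraries 1 and 2 and STING library 3 against the rest.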
